A study of Mus musculus with 30 samples.

How the data were processed

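The data were RNA sequencing libraries of mouse bone marrow cells, 2 fractions (LSK and Lin-negative) by 3 Tet2 genotypes (WT, Mut and KO) by 4 ages (3, 6, 9 and 12 months), with 1 library for each combination, 24 in all. The strain is labelled Mixed 129/C57BL/6, and per the design text the marrow of 3 mice was pooled for each library. Another 6 samples of whole-genome bisulfite sequencing at 3 months were not analysed here. Groups were taken from the titles and the genotype and cell type labels, and table columns were matched to samples by name. The description code of the 12-month LSK Mut sample ends in the letter that marks KO elsewhere, while its title, genotype label and column name give Mut, and it was used as Mut. The table held 0 columns of other samples.

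The deposited values are a signal, gene read counts divided by 1 size factor per library by the authors. Trim Galore 0.6.5, STAR 2.7.3a, featureCounts and edgeR are named for these samples with the build mm10, per the submitters' processing notes, which do not give their roles or order, and Bismark 0.22.3 is named there too. The annotation, the strand setting, the way reads with several matches were counted, and the rule by which genes were left out before deposit are not given in the sources used here. In the deposited table each column is made of whole multiples of 1 step, so whole reads were recovered: 100% of values were whole within 0.000001 reads. The size factors, from 0.8164 to 1.231, equalled median-of-ratios factors. The table holds 16070 genes, of which 740 have a 0 in at least 1 library, and the smallest mean of a gene over the libraries was 8.902. Library totals were 31455530 to 47713130 reads, and whether depth or the spread between pools limited single genes was not tested. Symbols were used as in the table, 14763 (91.9%) matched the reference annotation, and 17 members of the fixed lists (histones) were found under another symbol. Coordinates are those of the GRCm38 reference table, the same assembly as mm10.

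Because the unit is a normalized value, limma 3.58.1 (R 4.3.3, empirical Bayes with a mean-variance trend) on log2(value + 1) was the main test. Genes with a value of at least 10 in at least 4 libraries of the fit were tested, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Log2 differences are on this scale, which understates changes of low genes. Genotypes were compared within each fraction over its 12 libraries with age as a factor. Fractions were compared over all 24 libraries with the genotype and age combination as a block, and interactions and age trends (slope per month, genotype as a factor) were fitted likewise. The 4 ages stand in for replicates of a genotype. With age as a factor, p-values of genotype comparisons measure how far the genotype differences vary from age to age. A library of 1 pool carries no estimate of the spread within an age. Intervals cover the spread between libraries only. Recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0.

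The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For each genotype comparison the rule takes the 10 largest rises and 10 largest falls among genes past the threshold with the same sign at all 4 ages and a mean log2 of at least 2, the 5 smallest p where fewer than 5 genes pass, up to 4 passing members of each list, and Tet1, Tet2 and Tet3. For age trends it takes the 5 largest changes each way. Some genes the rule takes are not reported here. Which genes of this set the text names was chosen after their values were seen, genes at 0 in all WT libraries or with near-identical copies were mostly left out, and the members of the count of 5 and 3 between KO and Mut are all named. Other genes named in the text (Kit, Hlf, Lck, the Y-linked genes and the granulocyte markers) were chosen after their values were seen.

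The 21 lists were TET and DNA methylation enzymes, long-term stem cell, aged stem cell, Hox cluster, granulocyte, monocyte and macrophage, dendritic cell and MHC class II, erythroid, megakaryocyte and platelet, B lymphoid, T and NK cell, mast cell, basophil and eosinophil, stromal and endothelial, cell cycle, interferon response, inflammatory and NF-kappaB, immediate early and handling stress, p53 target, mitochondrially encoded, sex-linked, and replication-dependent histone genes. They were tested with limma's camera (preset correlation 0.01, adjusted over the lists), with camera and an estimated correlation, and with fry, which tests whether a list moves one way on balance and does not compare it with other genes. Against WT, fry called 9 lists for Mut and 5 for KO in LSK cells, and 5 and 3 in Lin-negative cells. It called 0 for KO against Mut in either fraction and 0 for both interactions. For the fractions it called 1, and for the age trends 6 in LSK and 13 in Lin-negative cells. A list's median, mean and camera direction differed in sign in 16 of the list tests, none of which passed camera.

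Sex composition was checked after the values of Xist and the Y-linked genes were seen, and the Y index was then added as a covariate. Comparisons that share WT libraries were set against 20 simulations of unchanged groups. Each comparison was tested on simulated counts with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. In the simulated LSK comparison of Mut with WT (15948 genes) 58.2%, 67.2% and 92.4% of these were recovered, and 9.38% of 160 calls were false. For Lin-negative KO against WT (15906 genes) the shares were 20.9%, 74.6% and 90.9%, for LSK against Lin-negative (16059 genes) 77.6%, 91% and 98.5%, and for the LSK age trend (15914 genes) 10.4%, 43.3% and 80.3%. Apart from the set changes, the simulated counts held no age, sex or pool effect and no correlation between genes. These shares therefore do not carry over to the real libraries. Alternatives were the pseudocount, the filter, the normalization, the variance model, the age term, the libraries in the fit, count tests, and leaving out each library and each age. For fractions, interactions and age trends the count tests and the left-out libraries or pairs were added after seeing the data.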

Results

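RNA sequencing measured gene expression in blood-forming cells sorted from the bone marrow of mice with normal Tet2 (WT), with a Tet2 protein that lacks catalytic function (Mut) or without Tet2 (KO). Tet2 encodes an enzyme that oxidises 5-methylcytosine in DNA. LSK cells are lineage-negative, Sca1-positive, cKit-positive stem and progenitor cells, and Lin-negative cells are the wider population depleted of mature blood cells. Each of the 6 combinations of fraction and genotype had 4 libraries, 1 at each of 3, 6, 9 and 12 months of age, and each library came from the pooled marrow of 3 mice. The table gave normalized read counts of 16070 genes in 24 libraries. Library totals ran from 31455530 to 47713130 reads.

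The targeted gene came first. In LSK cells the mean normalized count of Tet2 was 2044 ± 710 (SD, n = 4) in WT, 2606 ± 555 in Mut and 1757 ± 450 in KO. In Lin-negative cells it was 2073 ± 688 in WT, 2172 ± 887 in Mut and 1583 ± 705 in KO. The limma log2 difference from WT was 0.39 (adjusted p = 0.0664) in LSK Mut and -0.19 (adjusted p = 0.443) in LSK KO, and 0.03 (adjusted p = 0.959) and -0.43 (adjusted p = 0.233) in Lin-negative Mut and KO. Counts were summed over the whole gene, so they check neither a point change nor the loss of some exons, and genotypes are those of the labels. Tet1, a related enzyme, averaged 348.9 ± 103 in WT, 327.8 ± 27.7 in Mut and 304.4 ± 42.5 in KO LSK cells, and 333.3 ± 121.9, 244.8 ± 42.2 and 254.2 ± 72.1 in Lin-negative cells. Tet3 averaged 4425 ± 586, 5391 ± 166 and 4922 ± 395 in LSK cells, where the rise in Mut passed the limma test (0.29, adjusted p = 0.0434), and 4673 ± 582, 4373 ± 1079 and 3737 ± 1006 in Lin-negative cells, where no difference passed.

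Expression of Y-linked genes differed between the pools. The Y index, the summed normalized count of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty over its largest value, averaged 0.356 ± 0.397 (SD, n = 4) in WT, 0.725 ± 0.192 in Mut and 0.612 ± 0.351 in KO LSK libraries. The corresponding Lin-negative values were 0.299 ± 0.306, 0.616 ± 0.185 and 0.432 ± 0.272. The difference between Mut and WT had a two-sided exact permutation p of 0.171 in LSK and 0.143 in Lin-negative libraries, where the smallest possible p was 0.029. For KO and WT the permutation p was 0.314 and 0.486. These permutations ignore age. Mut was above WT at 6, 9 and 12 months and below it at 3 months in both fractions. In LSK libraries KO was above WT at every age (1 and 0.917, 0.811 and 0.176, 0.377 and 0.331, 0.259 and 0). In Lin-negative libraries KO was below WT at 3 months (0.279 and 0.717). The 12-month WT libraries of both fractions had an index of 0. Counts of changed genes are also given with this index in the model, an alternative chosen after seeing the data.

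**Figure D1:**
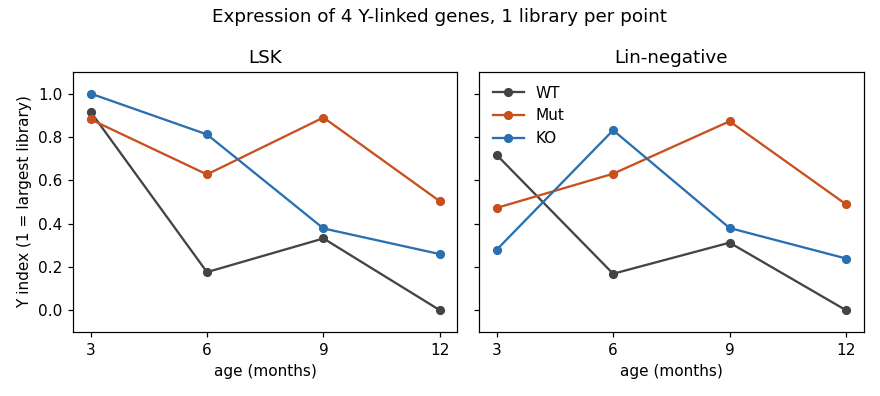
Y index of each library (vertical axis, the summed normalized count of 4 Y-linked genes relative to the largest library) against age in months, 1 point per library, with lines joining the libraries of 1 genotype. The LSK libraries at 3 months have indices of 0.917, 0.881 and 1, while the WT libraries at 12 months are at 0.

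The first comparison asked how LSK cells differed when Tet2 lacked its catalytic function. Monocyte and macrophage genes rose in Mut LSK cells. Ctss, a lysosomal protease, rose from 7694 ± 2085 to 12795 ± 1529 (log2 difference 0.76, SE 0.133, n = 4 per genotype, limma adjusted p = 0.00744), and Axl, a receptor tyrosine kinase, rose by 1.18. Adgre1, which encodes F4/80, rose by 0.74. Of the 20 measured genes in this list 12 rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 1.76e-09, but adjusted p = 0.264 with an estimated correlation). Among 18 dendritic cell and MHC class II genes 9 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000229, adjusted p = 0.333 with an estimated correlation). These included Ciita, the main activator of MHC class II transcription (1.69, limma adjusted p = 0.00284), and H2-Aa (1.13) and H2-Eb1 (1.25), which encode MHC class II chains. Cd74, the invariant chain, rose by 1.14 (limma adjusted p = 0.014) but was higher at 3 of 4 ages.

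Genes of interferon and inflammatory signalling were higher in Mut LSK cells over the 4 ages together. By age, with 1 library per genotype, the interferon list had medians of -0.00604, 0.537, 1.46 and 0.571 at 3, 6, 9 and 12 months, and the inflammatory list 0.00302, 0.411, 0.936 and 0.309. The T and NK cell and immediate early lists were at -0.198 and -0.0329 at 3 months. In Lin-negative cells the interferon median at 3 months was 0.964, and a difference of these lists between ages was not tested. Of 24 interferon response genes 10 rose and none fell, or 16 and none adjusted over the list alone (camera adjusted p = 1.76e-09, adjusted p = 0.345 with an estimated correlation). Gbp2, an interferon-induced GTPase, rose by 1.76, Zbp1, a sensor of unusual nucleic acids, by 1.30 and Xaf1 by 1.25. Of 20 inflammatory and NF-kappaB genes 6 rose, or 9 adjusted over the list alone, and none fell (camera adjusted p = 0.000229, adjusted p = 0.333 with an estimated correlation). They included the chemokine gene Cxcl10 (1.73, limma adjusted p = 0.00559) and the NF-kappaB subunits Nfkb2 (0.73) and Relb (0.75). Among 20 T and NK cell genes 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00349, adjusted p = 0.401 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, rose by 1.25 and Cd4 by 1.61. Pdcd1, which encodes the T cell checkpoint receptor PD-1, rose from 28.8 ± 9.09 to 634 ± 585 (log2 difference 3.73, SE 0.496, limma adjusted p = 0.00284), and Rgs16, a regulator of G protein signalling, rose by 3.58. Immediate early genes (20 measured, 5 rose, or 6 and 1 fall adjusted over the list alone) and p53 targets (15 measured, 3 rose by either adjustment) passed camera too (adjusted p = 0.00287 and 0.0295, but adjusted p = 0.401 and 0.345 with an estimated correlation). Without the 6-month libraries the T and NK cell, immediate early and p53 lists no longer passed (medians 0.182, 0.155 and 0.121), nor did they without WT at 6 months (0.312, 0.133 and 0.152). Without Mut at 6 months the T and NK cell and p53 lists did not pass (0.23 and 0.152). Egr2 rose by 1.82, and Cdkn1a, the cell cycle inhibitor p21, by 0.60.

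Erythroid, mast cell and cell cycle genes fell in Mut LSK cells. Of 21 erythroid genes 17 fell and none rose, and all 21 fell adjusted over the list alone (camera adjusted p = 8.46e-14, adjusted p = 0.264 with an estimated correlation). Gata1, the main erythroid transcription factor, averaged 1551 ± 158 in Mut against 2588 ± 365 in WT (log2 difference -0.73, SE 0.0984, limma adjusted p = 0.00284), and Rhd, a red cell membrane protein, differed by -0.82. Of 15 mast cell, basophil and eosinophil genes 11 fell by either adjustment (camera adjusted p = 4.3e-07, adjusted p = 0.264 with an estimated correlation). Prg2, an eosinophil granule protein, averaged 5834 ± 1555 against 13079 ± 3276 (-1.17, limma adjusted p = 0.00496), and Epx, an eosinophil peroxidase, differed by -1.15. Of 22 cell cycle genes 18 fell by either adjustment (camera adjusted p = 7.65e-11, adjusted p = 0.264 with an estimated correlation), with Cdk1 at -0.35 and Pcna at -0.35. Of 17 replication-dependent histone genes 3 fell by either adjustment (camera adjusted p = 0.00331, adjusted p = 0.401 with an estimated correlation), and this list no longer passed without WT at 9 months (median -0.147) or all 9-month libraries (-0.131). Hoxa9, a stem cell transcription factor, differed by -1.15 (limma adjusted p = 0.00284) and Gata2 by -0.70. Ly6a, which encodes the Sca1 antigen used to sort LSK cells, rose from 305 ± 121 to 1254 ± 923 (1.70, limma adjusted p = 0.0109). Ighg1, an immunoglobulin constant gene that resembles its neighbours and whose counts are therefore uncertain, averaged 188 ± 71.2 against 2810 ± 1173 (-3.89). The other 10 lists did not pass camera, with a smallest adjusted p of 0.0601. Among their members, 4 granulocyte genes fell (5 adjusted over the list alone), including Elane (-0.46) and Ms4a3 (-0.47).

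In all, limma called 2213 of 16007 genes between Mut and WT LSK cells, 1131 higher and 1082 lower in Mut, and 2081 of these had the same sign at all 4 ages. With the Y index in the model 115 genes passed, of which 97 were among the 2213, while the log2 differences of the 2213 genes kept a median ratio of 0.917 to those without the index and their median SE went from 0.093 to 0.128. The count was 100 without the 12-month libraries, 221 without the 9-month libraries, 473 without WT at 9 months, 561 without Mut at 12 months, 728 without Mut at 9 months, 764 without WT at 12 months and 1380 without Mut at 6 months. The count was 558 without the mean-variance trend, 129 with age as a number, 1104 with all 24 libraries in the fit and 1192 with only the 8 compared.

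The same question was asked of LSK cells without Tet2. Adgre1 rose in KO LSK cells by 0.83 (limma adjusted p = 0.0097) and Ctss by 0.60, while Vcam1, an adhesion molecule also found on marrow macrophages, differed by -0.67. Of the 20 monocyte and macrophage genes 5 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 4.09e-07, adjusted p = 0.328 with an estimated correlation). Of 24 interferon response genes 3 rose, or 16 adjusted over the list alone (camera adjusted p = 4.42e-10, adjusted p = 0.467 with an estimated correlation). Ifi27l2a, an interferon-induced gene, rose from 1407 ± 373 to 3228 ± 993 (SD, n = 4; log2 difference 1.18, limma adjusted p = 0.027), and Zbp1 rose by 0.99. Of 20 inflammatory genes none passed over all genes and 4 rose adjusted over the list alone (camera adjusted p = 0.027, adjusted p = 0.737 with an estimated correlation), and the list no longer passed without KO at 3 months, WT at 6 months, WT at 9 months or all 6-month libraries (medians 0.256, 0.222, 0.163 and 0.221).

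Of 21 erythroid genes 10 fell in KO LSK cells, or 20 adjusted over the list alone (camera adjusted p = 6.84e-14, adjusted p = 0.328 with an estimated correlation). Gata1 differed by -0.60, and Klf1, an activator of globin genes, by -0.56. Of 15 mast cell, basophil and eosinophil genes 9 fell, or 10 adjusted over the list alone (camera adjusted p = 2.14e-08, adjusted p = 0.328 with an estimated correlation), with Prg2 at -1.04 and Ms4a2, a chain of the IgE receptor, at -1.07. Of 22 cell cycle genes 2 fell, or 12 adjusted over the list alone (camera adjusted p = 2.68e-08, adjusted p = 0.328 with an estimated correlation). Hoxa9 differed by -1.04 and Gata2 by -0.66. Among the largest falls were Sec16b (-2.37, limma adjusted p = 0.0017) and Ighg1 (-3.40), and among the largest rises were Pdcd1 (2.11), Rgs16 (1.96) and Maob (2.39), an amine oxidase. The ribosomal pseudogene Rpl34-ps1 rose from 45.7 ± 29.9 to 3149 ± 1015 (6.20, limma adjusted p = 1.8e-07) and Gbp2b from 1.90 ± 2.55 to 305 ± 134 (7.04, adjusted p = 0.000611). Both resemble other genes, so their counts are uncertain.

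For KO against WT in LSK cells limma called 604 of 16007 genes, 331 higher and 273 lower in KO. DESeq2 called 1444 genes, and limma with the Y index 60, of which 57 were among the 604. With the index the log2 differences of the 604 genes had a median size of 0.453 against 0.483 (median ratio 0.933, 100% with the same sign), and their median SE was 0.116 against 0.0981. The count was 16 without the 12-month libraries, 47 without the 9-month libraries, 51 without WT at 9 months, 52 without WT at 12 months, 60 without KO at 9 months, 112 without KO at 3 months, 200 without KO at 12 months, 328 without the 6-month libraries, 343 without KO at 6 months, 1079 without the 3-month libraries and 1723 without WT at 3 months. Without the mean-variance trend it was 43, with age as a number 24, with all 24 libraries 218 and with only the 8 compared 233.

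**Figure D2:**
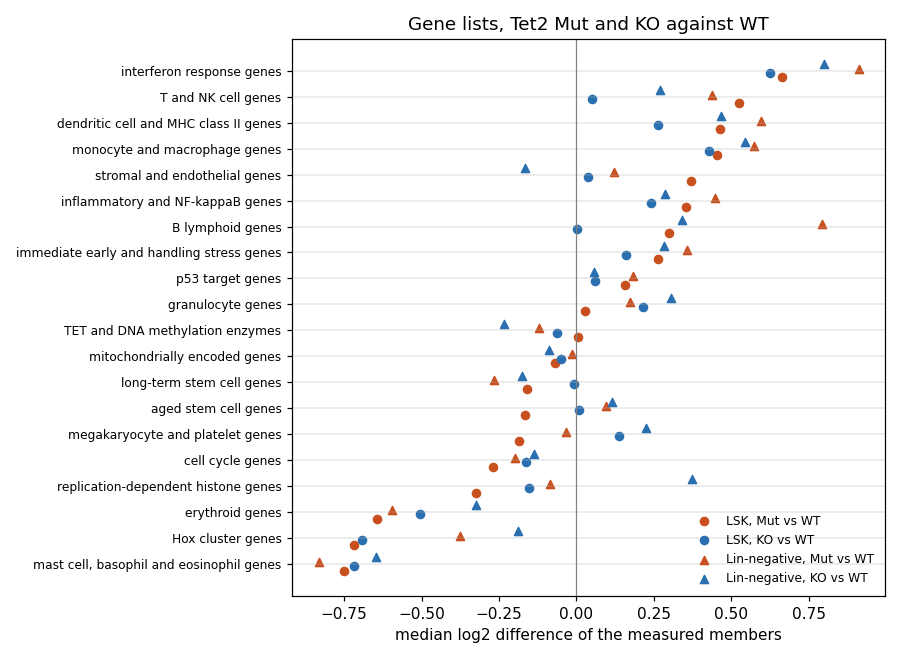
Median log2 difference from WT (horizontal axis) of the measured genes of 20 lists, for Mut and KO in LSK cells (circles) and Lin-negative cells (triangles). The interferon response and the monocyte and macrophage lists lie above 0 and the erythroid and mast cell lists below 0 in all 4 comparisons, and no list of these comparisons passed camera with an estimated correlation.

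Lin-negative cells were compared in the same way. In Mut against WT, C1qa rose from 240 ± 136 to 742 ± 285 (SD, n = 4; log2 difference 1.75, SE 0.234, limma adjusted p = 0.00492), and C1qb and C1qc, which encode the other chains of complement C1q, a macrophage product, rose by 1.85 and 1.72. Axl rose by 1.52. Of 20 monocyte and macrophage genes 9 rose, or 17 adjusted over the list alone (camera adjusted p = 1.82e-16, adjusted p = 0.0598 with an estimated correlation). Of 24 interferon response genes 13 rose, or 23 adjusted over the list alone (camera adjusted p = 2.49e-24, adjusted p = 0.184 with an estimated correlation). Gbp2 rose from 508 ± 137 to 2808 ± 1616 (2.27, limma adjusted p = 0.00128), Ifi27l2a by 1.52 and Zbp1 by 1.75. Of 18 dendritic cell and MHC class II genes 7 rose, including Cd74 (1.27) and H2-Ab1 (1.19), or 10 with 1 fall adjusted over the list alone (camera adjusted p = 9.1e-06, adjusted p = 0.217 with an estimated correlation). Of 20 inflammatory genes 4 rose, including Relb (1.04), or 7 adjusted over the list alone (camera adjusted p = 5.84e-06, adjusted p = 0.217 with an estimated correlation). Ly6a rose by 2.19.

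Of 21 erythroid genes 6 fell in Lin-negative Mut cells, or 16 adjusted over the list alone (camera adjusted p = 3.01e-12, adjusted p = 0.217 with an estimated correlation), with Ermap at -0.78, Klf1 at -0.66 and Gata1 at -0.63. Of 15 mast cell, basophil and eosinophil genes 8 fell, or 10 adjusted over the list alone (camera adjusted p = 1.24e-07, adjusted p = 0.217 with an estimated correlation), with Fcer1a, a chain of the IgE receptor, at -1.05 and Prg2 at -1.04. Hoxa9 differed by -0.92 and Gata2 by -0.83. Of 19 long-term stem cell genes 1 rose and 2 fell, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.0147, adjusted p = 0.217 with an estimated correlation). Of 10 Hox genes 1 fell, or 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0436, adjusted p = 0.217 with an estimated correlation). B lymphoid (20 genes, 1 rose, or 4 adjusted over the list alone), T and NK cell (20 genes, 2 rose, or 5) and p53 target lists (15 genes, 1 rose, or 2) passed camera upward, with adjusted p = 6.4e-06, 0.00021 and 0.0304, but adjusted p = 0.282, 0.3 and 0.3 with an estimated correlation. The immediate early list also passed upward (camera adjusted p = 9.1e-06, adjusted p = 0.217 with an estimated correlation), as did the cell cycle list downward (3.48e-07, adjusted p = 0.282 with an estimated correlation), with no single member past the threshold in either. The sex-linked list passed at camera adjusted p = 0.0331 (adjusted p = 0.344 with an estimated correlation). Without the 6-month libraries the T and NK cell (median 0.25), p53 (0.0963) and sex-linked (3.33) lists no longer passed, nor did the Hox list without the 3-month libraries (-0.457). The Hox list also failed without Mut at 3, 9 or 12 months or WT at 3 or 6 months, the p53 list without Mut or WT at 6 or 9 months or all 9-month libraries, and the sex-linked list without Mut at 6 or 12 months.

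For Lin-negative Mut against WT limma called 377 of 15982 genes, 254 higher and 123 lower in Mut. DESeq2 called 1077 genes, and limma with the Y index 66, of which 60 were among the 377. For these 377 genes the index changed the median size of the log2 difference from 0.865 to 0.791 (median ratio 0.9, 100% with the same sign) and the median SE from 0.152 to 0.177. The count was 41 without the 9-month libraries, 86 without WT at 9 months, 92 without WT at 6 months, 105 without WT at 12 months, 111 without Mut at 9 months, 164 without the 12-month libraries, 166 without the 6-month libraries, 221 without Mut at 6 months, 223 without Mut at 3 months and 646 without WT at 3 months. It was 98 without the mean-variance trend, 125 with age as a number, 975 with all 24 libraries and 690 with only the 8 compared.

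In Lin-negative KO cells C1qa rose by 1.67 against WT (limma adjusted p = 0.0103) and C1qb by 1.72. Of 20 monocyte and macrophage genes 5 rose, or 14 adjusted over the list alone (camera adjusted p = 2.05e-11, adjusted p = 0.148 with an estimated correlation). Of 24 interferon response genes 7 rose, or 20 adjusted over the list alone (camera adjusted p = 1.3e-17, adjusted p = 0.347 with an estimated correlation), with Ifi27l2a at 1.64 and Isg15, a ubiquitin-like modifier, at 1.17. Mgl2, a macrophage lectin, averaged 275 ± 48 in KO against 1017 ± 270 in WT (SD, n = 4; log2 difference -1.86, limma adjusted p = 0.000172). Ighg1 differed by -3.61 and Ighg2b by -1.95, both with uncertain counts. Of 15 mast cell genes 1 fell (Ms4a2, -0.97), or 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 6.73e-05, adjusted p = 0.395 with an estimated correlation). Mecom, a regulator of long-term stem cells, differed by -1.62 (limma adjusted p = 0.0477), the 1 of 19 long-term stem cell genes past the threshold, while 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0802). Rpl34-ps1 rose by 6.60, Gbp2b by 6.98 and Maob by 2.67, while Sec16b differed by -2.13.

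Other lists passed camera in Lin-negative KO cells without a single member past the threshold over all genes. They were the erythroid (adjusted p = 0.000462, adjusted p = 0.463 with an estimated correlation; 2 of 21 fell adjusted over the list alone) and cell cycle lists (0.00198, adjusted p = 0.464 with an estimated correlation) downward, which no longer passed without the 9-month libraries (medians -0.0976 and -0.073) or KO at 9 months (-0.154 and -0.11) or, for cell cycle, WT at 9 months (-0.0752), and the dendritic cell and MHC class II list upward (0.0042, adjusted p = 0.442 with an estimated correlation; 9 of 18 rose and 1 fell adjusted over the list alone). The granulocyte, inflammatory, immediate early, B lymphoid, T and NK cell, megakaryocyte and histone lists passed upward and the TET and DNA methylation list downward, at camera adjusted p from 0.000809 to 0.047, and none passed with an estimated correlation (adjusted p = 0.395 or more with an estimated correlation). Leaving out a library or age ended the call of each of these 8 lists at least once, except the granulocyte list. For this comparison limma called 93 of 15982 genes, 61 higher and 32 lower in KO, DESeq2 called 626, and limma with the Y index 79, of which 72 were among the 93. The count was 17 without the 9-month libraries, 23 without WT at 9 months, 24 without KO at 9 months, 28 without the 6-month libraries, 33 without WT at 6 months, 34 without WT at 12 months, 37 without the 12-month libraries and 60 without KO at 6 months, and 37 without the mean-variance trend, 34 with age as a number and 441 with all 24 libraries.

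The overlap of Mut and KO was then counted. In LSK cells 292 of the 331 genes called higher in KO were also called higher in Mut, and 243 of the 273 called lower were also lower in Mut, against 23.4 and 18.5 for independent lists. No gene was called in opposite directions. In Lin-negative cells the overlaps were 50 of 61 and 24 of 32, against 0.969 and 0.246. Both comparisons share their WT libraries, so a WT pool that differs for another reason moves both. In 20 simulations of unchanged groups against shared controls the overlap was 0.05 genes on average in LSK cells and 0 in Lin-negative cells. Unchanged groups give almost no calls, so this result was fixed in advance. It cannot show how much the shared WT libraries add to the overlap. Across genes, which are not independent replicates, the log2 differences of Mut and KO correlated at 0.682 in LSK cells (simulated 0.5), with a covariance of 0.124 (simulated 0.0356, a difference of 0.0883), and at 0.241 to 0.363 when separate WT pairs served as controls. The Lin-negative values were 0.666 (simulated 0.502), a covariance of 0.139 (simulated 0.0436) and 0.268 to 0.457 with split controls.

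The direct comparison of KO with Mut asked what differed between the absence of Tet2 and the loss of its catalytic function. In LSK cells Rpl34-ps1 averaged 3149 ± 1015 (SD, n = 4) in KO against 44.1 ± 17.8 in Mut (log2 difference 6.16, limma adjusted p = 1.95e-07), and Gm5900 was higher in KO by 2.42 (adjusted p = 0.0262). Rpl34, a ribosomal protein gene that resembles Rpl34-ps1, averaged 6640 ± 2110 against 15909 ± 4470 (-1.28, limma adjusted p = 0.00011). Gbp2b, an interferon-induced GTPase gene, was higher in KO by 4.89 (limma adjusted p = 0.0262), but Mut at 6 months had a normalized count of 80.44 against 1.765 to 6.299 in the other 3 Mut libraries, and without it the difference was 5.71. Tesc, a calcium-binding protein gene, was higher by 1.23 (adjusted p = 0.0319). Reads of Rpl34 and its copy can be split between them, so both counts are uncertain. In Lin-negative cells Rpl34-ps1 (6.68), Gm5900 (2.45, adjusted p = 0.011) and Gbp2b (5.28, adjusted p = 0.0149) passed limma, while Rpl34 (-1.19, adjusted p = 0.0734) and Mcub (-1.24, adjusted p = 0.122) did not. In GRCm38 coordinates, Tet2 lies on chromosome 3 at 133463677 to 133545136, Rpl34 at 130726827 to 130730398, Mcub at 129914960 to 129970211 and Gbp2b at 142594816 to 142619179. Rpl34-ps1 lies on chromosome 6, Gm5900 on chromosome 7 and Tesc on chromosome 5.

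**Figure D3:**
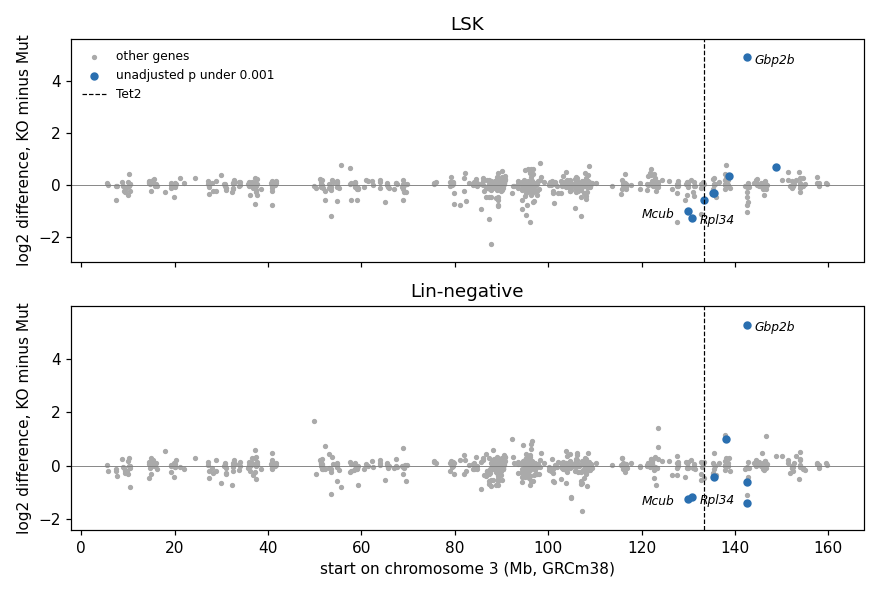
Log2 difference of KO minus Mut (vertical axis) for each measured gene of chromosome 3 against its start in Mb (GRCm38), in LSK cells (upper panel) and Lin-negative cells (lower panel). Larger points had an unadjusted limma p under 0.001, and in each fraction 7 of them lie within 20 Mb of Tet2 (dashed line).

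No fixed list had a member past the threshold over all genes between KO and Mut. Camera called 14 lists in LSK cells, including the megakaryocyte (median 0.292) and granulocyte (0.158) lists higher in KO, with 1 of 17 and 4 of 20 genes higher adjusted over the list alone, and the dendritic cell and MHC class II list (median -0.38) lower. It called 11 lists in Lin-negative cells, including the erythroid list (median 0.29) higher and the B lymphoid list (median -0.397) lower in KO, which no longer passed without KO at 9 months (-0.2), Mut at 9 months (-0.108) or all 9-month libraries (-0.0633). None passed with an estimated correlation (smallest adjusted p = 0.257 with an estimated correlation in LSK and 0.341 in Lin-negative cells). Limma called 5 genes in LSK and 3 in Lin-negative cells, and DESeq2 called 88 and 51. The LSK count was 2 with the Y index in the model, without the mean-variance trend or with age as a number, and 10 with only the 8 libraries compared, while the Lin-negative count was 8 with all 24 libraries and 1 with only the 8 compared. The LSK count was 13 without the 3-month libraries, 11 without Mut at 3 months, 3 without KO at 6 months, and 2 without KO at 3, 9 or 12 months, Mut at 9 or 12 months, or all libraries of 6, 9 or 12 months. The Lin-negative count was 10 without KO at 6 months, 8 without the 12-month libraries, 7 without Mut at 12 months or all 6-month libraries, and 1 without KO at 3, 9 or 12 months, Mut at 3 or 9 months, or all 9-month libraries.

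The fractions themselves were compared within the 12 pairs of libraries of 1 genotype and age. At 3 months the Y index differed within pairs (0.917 and 0.717 in WT, 0.881 and 0.472 in Mut, 1 and 0.279 in KO), so those pairs did not hold the same mix of mice. Kit, the receptor used to sort LSK cells, averaged 4818 ± 758 (SD, n = 12) in LSK and 4351 ± 905 in Lin-negative libraries, a log2 difference of 0.16 with a 95% interval of 0.0679 to 0.247, and was higher in LSK in 10 of 12 pairs (limma adjusted p = 0.123). Hlf, a stem cell transcription factor, was higher in 11 of 12 pairs (0.23, limma adjusted p = 0.126), while Ly6a, which encodes Sca1, differed by -0.285 (adjusted p = 0.18) and was higher in LSK in 3 of 12. S100a8 and S100a9, calcium-binding proteins of neutrophils and monocytes, differed by -0.195 and -0.184 and were among the most abundant transcripts of LSK libraries, with ranks from 2 to 6 and from 1 to 3. The long-term stem cell list had a median of 0.16 over 19 genes, with 4 higher adjusted over the list alone (camera adjusted p = 0.00305, adjusted p = 0.085 with an estimated correlation), and the B lymphoid list a median of -0.389 over 20 genes, with 9 lower adjusted over the list alone (8.34e-06, adjusted p = 0.488 with an estimated correlation). The erythroid, immediate early, cell cycle, histone, granulocyte, T and NK cell, dendritic cell and interferon lists passed camera lower in LSK, and none passed with an estimated correlation (adjusted p = 0.488 or more with an estimated correlation). Without the 3-month libraries the immediate early (-0.0127), dendritic cell (-0.0549) and interferon (0.00721) lists no longer passed. The interferon list also failed without the Mut (-0.0189) or KO (-0.103) pair of 3 months, the dendritic cell list without the WT pair of 3 months (-0.1) and the histone list without the 6-month libraries (-0.16). Limma called 0 of 16061 genes (smallest adjusted p = 0.123), with 3581 at an unadjusted p under 0.05, edgeR called 0, and DESeq2 called 672, 214 of them higher in LSK. The nearest library of 18 of the 24 was the other fraction of the same genotype and age.

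**Figure D4:**
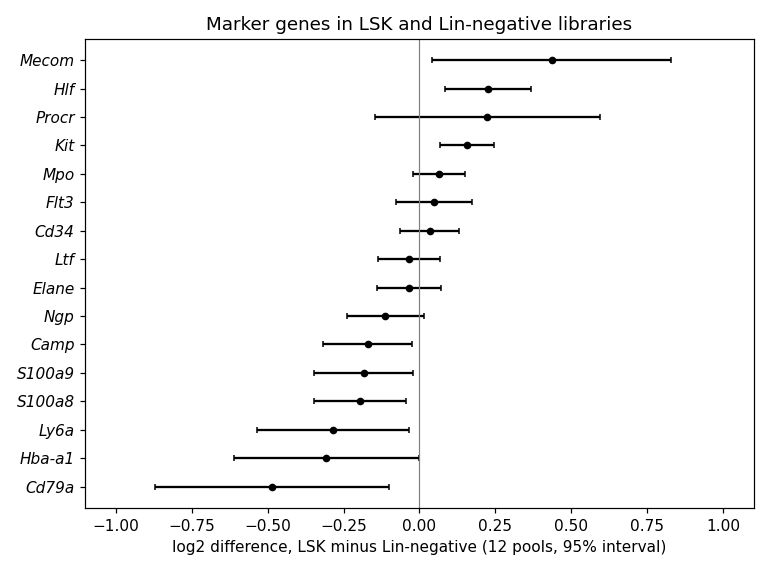
Log2 difference of LSK minus Lin-negative libraries (horizontal axis) for 16 marker genes, as the mean of 12 pairs of libraries with its 95% interval from limma. Kit lies at 0.157 and S100a8 at -0.195, and no gene passed the adjusted threshold.

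Whether a genotype effect differed between fractions was tested as an interaction. Limma called 0 of 16061 genes for Mut against WT (956 at an unadjusted p under 0.05, edgeR 0, DESeq2 0) and 0 for KO against WT (2144, edgeR 0, DESeq2 0). Limma's camera test called 6 lists for Mut, including the interferon list, whose LSK difference was lower than its Lin-negative one by a median of -0.325 (adjusted p = 8.49e-06), and the granulocyte (-0.147), B lymphoid (-0.334) and histone (-0.277) lists lower and the TET (0.157) and stromal (0.369) lists higher. For the interferon list the median was 0.0204 without the 3-month libraries (adjusted p = 0.995), -0.0764 without the WT pair and -0.0616 without the Mut pair of 3 months, none of which passed. The other calls each failed in at least 1 of these fits too: granulocyte without the Mut pair of 12 months (-0.0786), B lymphoid without the WT pair of 3 months (-0.12), histone without the Mut pair of 12 months (-0.0891), TET without the Mut pair of 12 months (0.061) and stromal without the 3-month libraries (0.318). None passed with an estimated correlation (smallest adjusted p = 0.572 with an estimated correlation). It called 12 lists for KO, including the histone list (median -0.614, adjusted p = 5.9e-07) and the B lymphoid list (-0.233), and none passed with an estimated correlation (smallest adjusted p = 0.286 with an estimated correlation). By age, with 1 library per group, the KO minus WT median of the B lymphoid list in LSK and Lin-negative cells was -0.532 and 0.845 at 3 months, where the pairs did not hold the same mix of mice, 0.405 and 0.39 at 6, -0.274 and 0.163 at 9 and -0.0739 and 0.107 at 12 months. The erythroid list (median -0.233) turned to 0.0767 without the 3-month libraries, 0.0849 without the KO pair of 3 months and 0.0755 with the Y index, and the interferon list (-0.164) to 0.0754 without the WT pair of 3 months, none of which passed. The mast cell, dendritic cell, stromal and sex-linked calls also failed in at least 1 of the fits without an age or a pair. Of the genes measured in both fractions and called for Mut, 303 were shared with the same sign and 0 with opposite signs. For KO these counts were 56 and 0. The fractions of 1 genotype and age had like Y indices at 6, 9 and 12 months, so a difference between pools can recur in both, and the overlap is no independent repeat.

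Age trends were fitted over 3 to 12 months with the 3 genotypes pooled. B lymphoid genes fell with age in both fractions. In LSK cells, however, no gene of any kind passed limma with the Y index in the model or without WT at 3 months. Rag1, which starts antigen receptor gene rearrangement, averaged 371 ± 169 (SD, n = 3) at 3 months and 20.2 ± 12 at 12 months in LSK cells (log2 slope -0.48 per month, limma adjusted p = 0.00677), and 707 ± 244 and 15.4 ± 2.23 in Lin-negative cells (-0.62 per month, adjusted p = 0.000183). Pax5, the B cell identity factor, had slopes of -0.62 and -0.70, and Igll1, a part of the pre-B cell receptor, of -0.57 and -0.62. Of 20 B lymphoid genes 12 fell in LSK and 18 in Lin-negative cells, or 17 and 19 adjusted over the list alone. The list passed camera in both (adjusted p = 1.18e-16 and 3.97e-30), with adjusted p = 0.119 with an estimated correlation in LSK and 0.0172 in Lin-negative cells. The plasmacytoid dendritic cell gene Siglech fell too (-0.24 and -0.32), as did the neutrophil chemokine receptor gene Cxcr2 (-0.17 and -0.21) and the cytokine gene Il1b (-0.28 and -0.31).

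Some genes of the aged stem cell, erythroid and megakaryocyte lists had rising slopes, none of which passed in LSK cells with the Y index in the model. Vwf, a platelet and stem cell gene, rose in LSK cells from 376 ± 89 (SD, n = 3) at 3 months to 1330 ± 190 at 12 months (slope 0.18, limma adjusted p = 0.00692), and Pf4, a platelet chemokine, had slopes of 0.23 in LSK and 0.26 in Lin-negative cells. Of 20 aged stem cell genes 6 rose and 1 fell in LSK cells, or 12 and 1 adjusted over the list alone, and 3 rose in Lin-negative cells, or 4 adjusted over the list alone. This list passed camera (adjusted p = 5.35e-06 and 0.000113) also when the correlation was estimated, with adjusted p = 0.0442 with an estimated correlation in LSK and 0.0172 in Lin-negative cells. Of 19 long-term stem cell genes 2 rose in each fraction, or 4 and 8 adjusted over the list alone (camera adjusted p = 3.87e-05 and 4.2e-06), with adjusted p = 0.0639 with an estimated correlation in LSK and 0.0172 in Lin-negative cells. Of 21 erythroid genes 16 rose in LSK and 5 in Lin-negative cells, or 20 and 19 adjusted over the list alone (camera adjusted p = 2.39e-18 and 1.31e-13), with adjusted p = 0.0639 and 0.129 with an estimated correlation. Slc4a1, the red cell anion exchanger, had slopes of 0.21 and 0.20. Of 17 megakaryocyte and platelet genes 6 rose in LSK cells, and 7 rose and 1 fell in Lin-negative cells (camera adjusted p = 0.0022 and 0.000323, adjusted p = 0.442 and 0.196 with an estimated correlation), with 9 higher and 3 lower, and 11 and 3, adjusted over the list alone. The megakaryocyte list no longer passed camera without the 3-month libraries (median slopes 0.0436 and 0.00809) or, in LSK, the 12-month libraries (0.069), nor the aged stem cell list in Lin-negative cells without the 12-month libraries (0.0514).

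Further lists passed camera with age and were lost with an estimated correlation. In Lin-negative cells the interferon list fell (4 of 24 genes, or 10 adjusted over the list alone; camera adjusted p = 1.85e-07, adjusted p = 0.196 with an estimated correlation), the inflammatory list fell (7 of 20, or 8; adjusted p = 0.196 with an estimated correlation) and the mast cell list rose (4 of 15 with 1 fall, or 11 and 1; adjusted p = 0.196 with an estimated correlation), with Prg2 at 0.21. In LSK cells the granulocyte list fell (5 of 20 with 1 rise, or 8 and 3 adjusted over the list alone; adjusted p = 0.368 with an estimated correlation). Without the 3-month libraries the Lin-negative interferon (-0.0168) and mast cell (0.0349) lists did not pass, and without the 12-month libraries neither the Lin-negative inflammatory (0.00506) nor the LSK granulocyte list (-0.0691). Limma called 737 genes with a trend in LSK cells, 224 rising and 513 falling, and 740 in Lin-negative cells, 131 rising and 609 falling. DESeq2 called 1647 and 1461, and with the Y index in the model 0 LSK genes passed limma and 393 Lin-negative genes, of which 370 were among the 740. The index changed the slopes of the 737 LSK genes from a median size of 0.0967 to 0.0834 (median ratio 0.872, 99.9% with the same sign), while their median SE went from 0.0202 to 0.0341. All 3-month LSK libraries had a Y index of 0.881 or more, and the female-specific Xist was among the rising LSK genes (1.37, limma adjusted p = 0.0183).

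**Figure D5:**
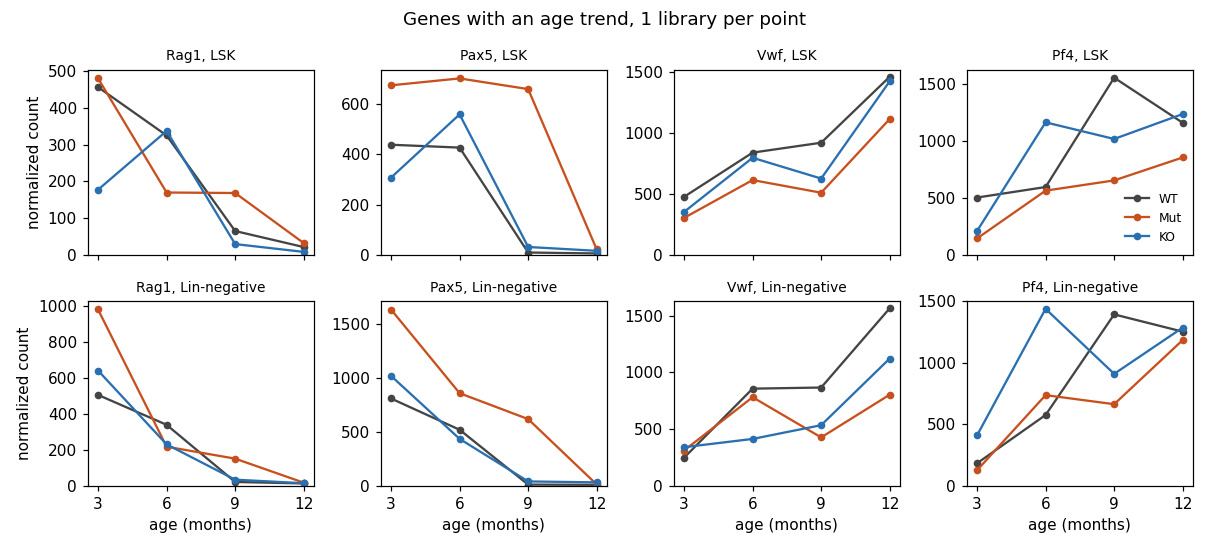
Normalized count (vertical axes) of Rag1, Pax5, Vwf and Pf4 against age in months in LSK (upper row) and Lin-negative cells (lower row), 1 point per library, with lines joining the libraries of 1 genotype. Mean Rag1 in LSK cells was 371 at 3 months and 20.2 at 12 months.

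The LSK trend count was 336 without the mean-variance trend and 468 with log2 of months. It was 0 without WT at 3 months, 111 without the 3-month libraries, 135 without KO at 12 months, 151 without WT at 12 months, 206 without Mut at 12 months, 345 without the 12-month libraries, 373 without the 6-month libraries, 408 without KO at 3 months and 1829 without the 9-month libraries. The Lin-negative trend count was 0 without the 3-month libraries, 191 without WT at 3 months, 326 without WT at 12 months, 351 without the 6-month libraries, 402 without Mut at 3 months, 431 without KO at 12 months, 442 without Mut at 12 months, 1352 without the 12-month libraries and 1622 without the 9-month libraries. The share of reads in mitochondrially encoded genes was 1.9% ± 0.255 (SD, n = 6) at 9 months, against 0.966%, 0.971% and 0.956% at 3, 6 and 12 months. A difference of the trend between genotypes was tested last. Limma called 0 genes in LSK cells (104 at an unadjusted p under 0.05, edgeR 0, DESeq2 0) and 0 in Lin-negative cells (227, edgeR 0, DESeq2 16). Without WT at 9 months the counts were 4 in LSK and 3 in Lin-negative cells, and without the 9-month libraries 1 LSK gene passed. On simulated data this test recovered 0% of genes changed 4-fold in LSK and 3.03% in Lin-negative cells, so it had almost no power.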

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

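The tests of other splits of the samples were planned, and the tests of the 3 patterns weighed here were chosen after the results were seen. Single libraries were compared with the other 3 of their group by the gap to the nearest divided by the range of all 4 (critical value 0.829). Chance gives about 1 in 20, and 19 of 254 groups passed, where 12.7 would by chance. The mitochondrial share of reads stood apart at 9 months in LSK WT (1.845%, ratio 0.92), Lin-negative WT (2.22%, 0.871) and Lin-negative KO (2.175%, 0.902), and the granulocyte share in LSK Mut at 12 months (5.12%, others 6.812% to 6.902%, ratio 0.949). Gbp2b stood apart in LSK Mut at 6 months (80.44, others 1.765 to 6.299, ratio 0.942) and in Lin-negative KO at 12 months (151.5, ratio 0.843). At 9 months Adgre1 in LSK KO (2099, ratio 0.843), Axl in LSK Mut (1776, 0.855), Cdk1 in LSK WT (6153, 0.912), Ighg1 in Lin-negative Mut (89.47, 0.843) and Tet2 in Lin-negative WT (3098, 0.875) did so. At 3 months these were C1qb in Lin-negative KO (1014, 0.896), Cxcl12 in LSK WT (490.8, others 27.99 to 78.94, ratio 0.89), Sparc in LSK WT (38.31, 0.937) and LSK Mut (77.33, 0.84), Maob in LSK KO (76.19, 0.887) and Tet3 in LSK KO (5515, 0.946). At 6 months they were Ighg2b in Lin-negative WT (8986, 0.837) and Tet1 in LSK KO (240.9, 0.89).

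Other splits of the same 8 libraries were counted to ask how many genes chance could give. For LSK Mut against WT 1 of 35 splits, the real one, gave as many genes as the 2213 called, and the highest other gave 208. For LSK KO against WT this was 1 of 35 (604, highest other 12) and for Lin-negative KO against WT 1 of 35 (93, highest other 1). In these 3 comparisons the share was under 0.05. It does not exclude chance, because most of the 35 splits are uneven in age and so unlike the real one. No split separates genotype from other differences between the pools. For Lin-negative Mut against WT 2 of 35 splits gave as many, and the other, which set WT at 3 months and Mut at 3, 9 and 12 months against the rest, called 547 against the real 377, so chance was not excluded by the 35 splits. That split put Y indices of 0.717, 0.472, 0.872 and 0.489 against 0.168, 0.312 and 0 in WT and 0.63 in Mut at 6 months. It parts the Y index too, so an effect of sex cannot be told apart from chance here. The same split was the highest other for LSK Mut against WT. For KO against Mut 2 of 35 splits gave as many in LSK (5, highest other 9) and 2 of 35 in Lin-negative cells (3, highest other 76), and the split with 76, Mut at 3, 6 and 9 months with KO at 9 months, points to a structure of the samples. Most of the 35 splits, those with 547 and 76 among them, are uneven in age, which the model fits as a factor. Among the 8 splits that, like the real one, part both libraries of each age, the highest other was 1 for Lin-negative KO against Mut and 0 for the other 5 comparisons of genotypes. These 8 are too few for a share under 0.05 in any of the 6 comparisons. Among 100 random draws of the age order within genotypes, with the real order counted as 1 of them, only the real order gave as many genes. This held in LSK (737, highest other 54) and in Lin-negative cells (740, highest other 10), so 1 of 100 in each. The share is under 0.05, but these draws move each genotype's ages separately. Moving all genotypes together gives 12 orders, of which 5 called as many in each fraction (highest other 3599 and 2022), so a trend cannot be separated from other differences between the age groups. For fractions (100 of 100), both interactions (35 of 35 each) and both genotype differences of the age trend (100 of 100 each), where 0 genes were called, all draws or splits gave as many.

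Libraries of LSK and Lin-negative cells of 1 genotype and age were nearly alike in most pairs. Among genes at a mean of at least 100, those over 2-fold apart numbered 135, 228 and 347 in WT, Mut and KO at 3 months. They numbered 103 in KO at 6 months, 63 in Mut at 12 months and 1 to 13 in the other pairs. The tables argue against scatter that hides a large difference, since the 95% interval of the Kit difference ended at 0.247 on the log2 scale. They also argue against exchanged labels in some pools, which would leave large differences of either sign, because the stem cell list median ran from -0.0516 to 0.301 over the 12 pairs. Transcripts typical of maturing granulocytes were abundant in the LSK libraries, although the LSK gate is meant to remove such cells. Ltf averaged 309104 and Ngp 383148 there, against 4818 for Kit. Which cells this RNA came from was not tested. The share of reads in Ltf, Camp, Ngp, Lcn2, S100a8 and S100a9 averaged 4.91% in LSK and 5.31% in Lin-negative libraries, with a median ratio of 0.954 (range 0.753 to 1.06, 12 pairs). All 6 genes also stand in the granulocyte list. A true likeness of correctly sorted fractions would still leave the sort markers higher in LSK libraries. Kit differed by only 0.157, and Ly6a, which encodes Sca1, by -0.285 (95% interval -0.536 to -0.0347, higher in LSK in 3 of 12 pairs). These values argue against a large enrichment for such cells in the LSK libraries, as far as RNA follows the surface proteins. Results given for LSK cells are those of libraries with that label, and no biological explanation was tested.

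Many genes were called between Mut and WT in LSK cells. The tables argue against a different share of male mice as the whole cause for the called genes as a set. With the Y index in the model their log2 differences kept a median ratio of 0.917 (quartiles 0.726 to 1.11), though they were picked without it. At 3 months the Y indices were close (0.881 in Mut, 0.917 in WT). There 75.2% of 2450 genes called without that age kept their sign, against 61.2% of all genes. Their median log2 difference there, in the direction called, was only 0.183. Genes called without 6, 9 or 12 months had medians of 0.192, 0.747 and 0.773 at the age left out, where the indices were further apart. The difference at 3 months was thus small, and the check is weak. The erythroid (-0.463) and monocyte (0.235) medians at 3 months kept their direction. The interferon (-0.00604), inflammatory (0.00302) and T and NK cell (-0.198) medians did not, so the argument does not cover every list. Among other splits of these libraries the highest called 208 genes. It set WT at 3 months and Mut at 3, 9 and 12 months (Y indices 0.917, 0.881, 0.889 and 0.503) against the rest (0.176, 0.331, 0 and, in Mut at 6 months, 0.627). In Lin-negative cells this split called 547 genes against the real 377, so a part played by the share of males stays open. With the index in the model the calls dropped to 115. The median SE of the called genes went from 0.093 to 0.128 and the median size from 0.414 to 0.383. The index and the genotype overlap in this design, which alone raises the SE by a ratio of 1.44. How much of the drop in calls comes from this was not tested. A different mix of cells could also be the cause. The lineage-negative LSK gate is meant to remove mature cells, but S100a8 and S100a9 were abundant in LSK libraries (ranks from 2 to 6 and from 1 to 3). The gate is therefore no argument against such a mix. T cell genes rose unequally (Cd3d 0.89, Cd3e 0.94, Cd3g 1.25, Cd4 1.61, Lck 0.55, of which Lck did not pass), a range of 1.06. That range cannot be told apart from a change within such cells, because bulk libraries do not show which cells the RNA came from, and an effect of the genotype itself also stays open.

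Few genes differed between KO and Mut, some of them near Tet2. The tables argue against reads moved from Rpl34 to Rpl34-ps1 and Gm5900 as the whole cause of its fall, because the sum of the 3 still differed between KO and Mut by -0.703 (log2, 95% interval -0.977 to -0.428) in LSK and -0.631 (-1.09 to -0.168) in Lin-negative cells. This covers only reads moved to these copies. Reads matched to other copies, or dropped for having several matches, would also lower the sum. How such reads were counted is not given, so the sum does not show that expression of Rpl34 itself fell. DNA of another strain around Tet2 may account for some, since 7 of the 34 LSK genes at an unadjusted p under 0.001 lay within 20 Mb of Tet2 (0.321 expected, one-sided Fisher's exact p = 2.51e-08), and 7 of 25 in Lin-negative cells (0.235, exact p = 2.32e-09), in a strain labelled as mixed. Against WT in LSK cells, 11 such genes lay there for Mut (8.21 expected, exact p = 0.199) and 9 for KO (3.81, exact p = 0.0143). In Lin-negative cells these were 7 (3.24, exact p = 0.0443) and 5 (1.93, exact p = 0.0442). Fisher's test takes genes as independent, which genes that change together are not, so these p-values overstate the evidence. The interferon-induced genes Gbp2, Gbp2b and Gbp3 were among the Lin-negative genes of KO against Mut, and Gbp2, Gbp5 and Gbp7 among those of LSK Mut against WT. A shared interferon change was not separated from DNA of another strain. Which line would carry such DNA was not settled. Reads assigned to a copy as a part of the fall, or as the source of the rise of both copies, stay open, untested, as does an effect of the missing Tet2 protein on nearby genes.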

How the results depend on the processing

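The tests with the Y index, and the count tests and left-out libraries for fractions, interactions and age trends, were chosen after the results were seen. The other pseudocounts, the filters, the recomputed normalization and edgeR on recovered reads kept all counts of changed genes within 1.5 times, and no named gene reversed under any alternative. Named genes past the threshold kept their direction in 6276 of 6276 refits chosen beforehand, 4292 past the threshold and 1984 not. In refits added later they did so in 1765 of 1765, 1187 and 578. For genotype comparisons, many of these genes were named because they had large changes with the same sign at every age. Leaving out an age could not turn such genes. The absence of reversals was therefore partly set by the selection and is no test of robustness. Whether they stayed past the threshold was not fixed in this way. Lists called by camera kept their call in 1923 of 2145 refits chosen beforehand, lost it in 216 and turned in 6, and in 785 added later these were 697, 85 and 3. For the values that changed, the cause was not tested, except that leaving out libraries leaves fewer samples.

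Without the mean-variance trend 558, 43 and 2 genes were called in LSK cells (Mut against WT, KO against WT, KO against Mut), 98 and 37 in Lin-negative cells (Mut and KO against WT) and 336 for the LSK age trend. With age as a number the counts were 129, 24 and 2 in LSK and 125 and 34 in Lin-negative cells. With all 24 libraries in the fit they were 1104 and 218 in LSK (Mut and KO against WT) and 975, 441 and 8 in Lin-negative cells. With only the 8 libraries compared they were 1192, 233 and 10 in LSK, and 690 (Mut against WT) and 1 (KO against Mut) in Lin-negative cells. DESeq2 on recovered reads called 1444 (LSK KO against WT), 88 (LSK KO against Mut), 1077, 626 and 51 (Lin-negative), 672 (fractions), 1647 and 1461 (age trends in LSK and Lin-negative cells) and 16 (genotype by age in Lin-negative cells). With the Y index the counts were 115, 60 and 2 in LSK, 66 for Lin-negative Mut against WT, and 0 and 393 for the age trends. With log2 of months the LSK age trend called 468.

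The replicate block is age, as libraries that share a number share an age. Without it the counts were 21, 14 and 2 in LSK and 73 and 19 in Lin-negative cells (Mut and KO against WT). Same-age libraries of 2 genotypes deviated together from their group means with a correlation of 0.0218 to 0.626, over 0.1 in 23 of 24 cases, which does not show pairing beyond the age itself. Age was fitted as a factor because the labels give it. Not every library correlated best with its own age: 22 of 24 cases did, as a hint from the data.

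Leaving out 1 library or age gave 100 to 2761 genes for LSK Mut against WT, 16 to 1723 for LSK KO against WT, 2 to 13 for LSK KO against Mut, 41 to 646, 17 to 133 and 1 to 10 for the same comparisons in Lin-negative cells, 0 to 1829 and 0 to 1622 for the age trends, and 0 to 4 and 0 to 3 for genotype by age. Some list medians turned. The interferon list in the Mut interaction, -0.325 with all libraries, ran from -0.454 without 6 months to 0.0204 without 3 months, and in the KO interaction (-0.164) from -0.251 without WT at 6 months to 0.0754 without WT at 3 months. The erythroid list in the KO interaction (-0.233) ran from -0.354 without KO at 12 months to 0.0849 without KO at 3 months, with 0.0767 without 3 months, and was 0.0755 with the Y index. The cell cycle list had slopes of 0.026 in LSK and 0.0165 in Lin-negative cells, which became -0.00953 and -0.0198 without 12 months and reached 0.0299 without 6 months in LSK and 0.02 without KO at 3 months in Lin-negative cells. The inflammatory list in the LSK age trend (-0.0235) ran from -0.0719 without 3 months to 0.0293 without 12 months. For the immediate early list between fractions (-0.147) the medians ran from -0.203 without 6 months to -0.0127 without 3 months, where the camera direction turned. Whether depth, the number of libraries, or the mix of ages and sexes limits these results was not tested.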

Other observations

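The comparisons of pools and of single ages in this part were chosen after the results were seen, and the tests of genes and lists were not. Genes of the stromal and endothelial list rose in Mut LSK cells: Fn1, which encodes fibronectin, by 0.75, Cxcl12 by 1.18 and Sparc by 1.48 on the log2 scale (limma), 3 of 14 measured genes, while the list as a whole did not pass camera (adjusted p = 0.0601). At 3 months single libraries stood apart: WT for Cxcl12 (490.8, others 27.99 to 78.94) and Sparc (38.31, others 6.997 to 8.97), and Mut for Sparc (77.33, others 25.2 to 33.54). Without WT at 3 months the differences of Cxcl12 and Sparc were 1.53 and 1.65. None of the 3 genes passed without the 12-month libraries or with the Y index in the model. The aged stem cell list moved both ways in Mut LSK cells, with Aldh1a1, an aldehyde dehydrogenase, at -0.69 and Vwf at -0.59, but Nupr1, a stress-response gene, at 0.65, 3 higher and 3 lower of 20 genes (camera adjusted p = 0.491). Of the megakaryocyte list, Pf4 differed by -0.89 and Itga2b by -0.48, and Itgb3 by 0.28. Among TET and DNA methylation enzymes Uhrf1, which guides maintenance methylation, differed by -0.28 while Idh1 (0.26) and Ogt (0.26) rose.

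The Y index of the LSK and Lin-negative libraries of 1 genotype and age differed less at 6, 9 and 12 months (0.811 and 0.831 in KO at 6 months) than at 3 months, where it was 0.917 and 0.717 in WT, 0.881 and 0.472 in Mut and 1 and 0.279 in KO. Xist was 0, 3.772 and 4.482 in the 3-month LSK libraries of WT, Mut and KO and 2165, 5846 and 5248 in the Lin-negative ones. At 12 months Xist also differed between the Mut fractions (7795 in LSK and 3725 in Lin-negative cells), and the chi-square per gene of that pair was 67.7, against 26, 52.9 and 91.1 for the 3-month pairs of WT, Mut and KO and 55.3 for the 6-month KO pair. The library nearest to LSK Mut at 12 months was LSK KO at 12 months (r = 0.9832 across genes, which are not independent replicates). Its correlation with Lin-negative Mut at 12 months was also 0.9832, so the KO library was hardly nearer than the same genotype. The normalized count of Rpl34-ps1 in LSK Mut at 12 months was 50.32, against 1945 to 4383 in the 4 LSK KO libraries.

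In LSK cells the log2 differences of Mut from WT had an SD over 11314 genes of 0.338 at 3 months, 0.396 at 6, 0.527 at 9 and 0.405 at 12 months. Across genes, which are not independent replicates, its correlation with the mean difference at the other ages was 0.358 at 3 months and 0.55 to 0.672 at the other ages. Over the other 5 comparisons of genotypes this correlation ran from -0.254 to 0.655, the lowest in Lin-negative KO against Mut at 12 months, where 33.9% of all genes had the same sign as at the other ages. In LSK Mut against WT, of 2450 genes called without the 3-month libraries, 75.2% had the same sign at 3 months, against 61.2% of all genes. The median of their log2 differences at 3 months, in the direction called, was 0.183.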
